A study of Rattus norvegicus with 9 samples.

How the data were processed

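RNA was measured in 3 cell populations sorted from oligodendrocyte progenitor cultures of newborn rats. Per the labels they were cells positive for the O4 antigen and negative for NG2 (called O4 here), cells positive for both NG2 and A2B5 (NG2/A2B5), and cells positive for NG2 only (NG2). Each population has 3 one-colour arrays numbered I, II and III. The series text gives 3 cultures, but the labels do not tie the numerals to them, so the p-values measure the spread between these 9 arrays. Per the labels, total RNA was amplified by in vitro transcription, labelled and hybridised, and spiked controls were used for normalization. The scanner and the software that made the table are not given in the sources used here.

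The values analysed are the deposited scaled intensity of each probe, on a linear scale, for 35129 probes on 9 arrays. Array medians lay between 1.05 and 1.07, so no further normalization was applied. Values coded -9999 were treated as missing. On each array, values at or below 0 were set to that array's smallest positive value before taking log2. Of the probes, 16865 carry 1 gene symbol, 165 carry several symbols and 18099 carry none. The last 2 classes were left out, except in the alternative that tested all probes. Symbols were looked up by Entrez identifier in the RefSeq gene table of assembly GRCr8, which was used for names only. The identifiers of 16836 probes matched and 1 symbol was updated. Each gene was represented by the probe with the highest mean over the 9 arrays, which gave 12167 genes. Of these, 2 genes had too few values for some contrast. The number of arrays limits the precision.

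The pairwise contrasts and the F test over the 3 populations came from 1 linear model of the log2 values with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without a block for the numeral. This leaves 6 residual degrees of freedom, and the prior had 1.76. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors are given as SD within a population or as the standard error (SE) of a contrast. Intervals are 95% intervals of the contrast, unless named as bootstrap intervals. A gene counted as higher or lower in 1 population than in both others when both contrasts called it.

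The 27 gene lists were fixed before the data were examined, as were the contrasts, tests and the first set of other settings. They cover refilins and filamins, sort marker genes, progenitor, lineage transcription factor, premyelinating and myelin genes, galactolipid, ganglioside and cholesterol synthesis, the cell cycle and cell cycle exit, filopodia and actin regulators, actin cross-linking and adhesion, neural stem genes, notch, wnt and bmp targets, and channels and receptors. The rest are markers of astrocytes, microglia, neurons, endothelium, pericytes, fibroblasts, Schwann cells and ependyma, immediate early and heat shock genes, interferon response genes and matrix proteoglycans. Of 563 distinct genes in the lists, 470 were measured. Each list and contrast was tested with camera at its preset inter-gene correlation of 0.01, and the 81 tests were adjusted together. Members were also tested with p adjusted over the list alone, separately in each list and contrast. This does not adjust across the 81 list and contrast pairs, so some passes are expected without any change.

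Genes are named by a rule written before the data were examined. In each contrast it names up to 10 called genes per direction with the largest change whose arrays do not overlap between groups, leaving out provisional symbols. Where under 5 genes passed, it gives the 5 with the smallest p. It adds all measured refilin, filamin and sort marker genes, and the 3 members of each list with the smallest p. The text prints a part of the last group.

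The other settings written down then were quantile normalization, centring of array medians, leaving out genes under the 25th percentile of all probes, the mean of a gene's probes, all probes, the numeral as a fixed or a random block, only the 6 arrays compared, trend and robust variance estimates (statmod 1.5.0), a log2 fold limit of 1, plain pooled-variance statistics, and leaving out each array. The plain statistics used only the 6 arrays compared. For the lists, camera with an estimated correlation and fry were also run. The list tests used genes with a value on every array. Another 9 combinations, and fry and camera of the refilin and filamin list without Rflna, were added after the data were seen. Pairing by numeral was checked by correlating, between arrays of different populations, the deviations from population means. Splits of the arrays into other groups were refitted in the same way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

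The pipeline was tested on simulated data with the observed spread, in which 100 genes were changed by each of 2 sizes in 1 contrast. The model without a block recovered 19% of the genes changed 2-fold and 58% of those changed 4-fold, with 1 false call among 11825 unchanged genes. In 50 simulations without any change, fitted with the fixed block and trend and robust estimates, at most 1 gene was called in either contrast with NG2. Errors were drawn independently for each gene. Apart from the numeral effects, the simulations thus hold no variation that many genes of an array share.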

Results

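Oligodendrocyte progenitors are the glial cells that give rise to the myelin-forming cells of the brain. Arrays were recorded for 3 populations sorted from cultures of these cells by surface antigens: O4, NG2/A2B5 and NG2, with 3 arrays each. NG2 is the proteoglycan encoded by Cspg4, A2B5 marks gangliosides of early glial progenitors, and O4 marks sulfatides of later stages. The series is about refilins and filamins, the actin cross-linking proteins that refilins bind, and its design sets each population against the other two. On each array between 34926 and 34975 probes had a value, and the highest value lay between 509 and 756 intensity units. The probe intensities of lineage genes ranged widely: on the log2 scale Bcas1 averaged 7.93, Cnp 7.64, Cd9 6.87, Sox10 5.20 and Mag 3.66, but Mog -1.64 and Mbp -2.26. The astrocyte marker Gfap averaged -1.77. Signal also depends on the probe, so these values do not rank the genes by their RNA. Mbp, at a mean intensity of 0.209, read near the 25th percentile of the arrays (0.205 to 0.255).

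The first principal component of the 9 arrays held 27.8% of the variance and the second 16.8%, over 10149 genes. Along the first, the arrays grouped by numeral and not by population. Along the second, the NG2 array had the highest score within each numeral. The contrasts below come from a model without the numeral, and with the numeral as a fixed block 0 genes passed in any of them. Adding trend and robust estimates to that block, a setting chosen after the data were seen, called 75 genes higher and 49 lower in O4 than in NG2, 1 and 0 in O4 than in NG2/A2B5, and 67 and 28 in NG2/A2B5 than in NG2.

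**Figure D1:**
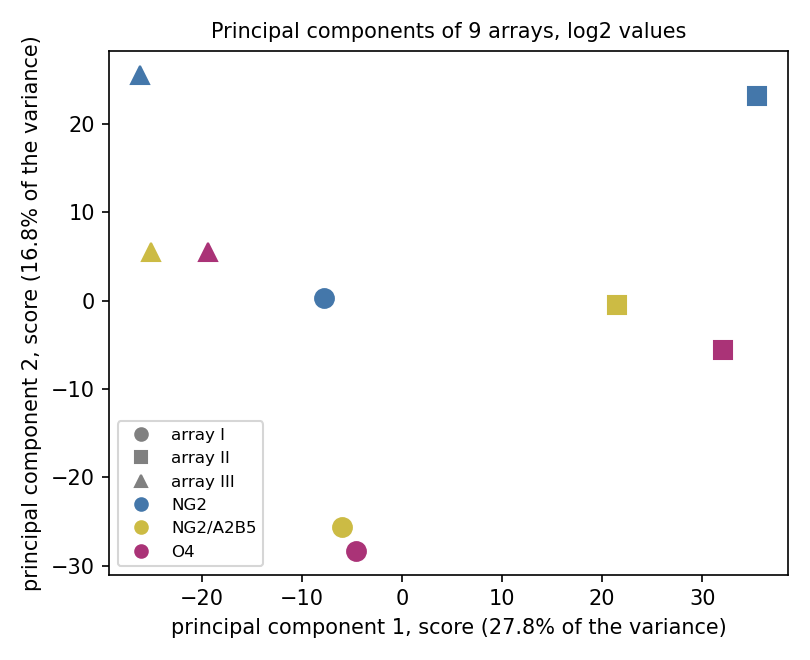
Scores of the 9 arrays on the first 2 principal components of the log2 values, coloured by population, with a marker shape for each numeral. The components hold 27.8% and 16.8% of the variance, and arrays with the same numeral lie together along the first.

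Refilin A, the product of Rflna, binds filamins and organises actin filaments, and its gene gave the clearest difference between the populations among the genes the series is about. Rflna measured 4.13 ± 0.22 on the log2 scale in O4 (SD, n = 3), 4.89 ± 0.28 in NG2/A2B5 and 2.18 ± 1.02 in NG2. Each NG2 array, from 1.13 to 3.16, lay under each array of the other populations. The difference was 1.95 for O4 minus NG2 (95% interval 0.88 to 3.02) and 2.71 for NG2/A2B5 minus NG2 (1.64 to 3.78), or 3.86-fold and 6.55-fold. By numeral I, II and III, the differences from NG2 were 1.21, 2.80 and 1.84 in O4, and 1.43, 3.81 and 2.89 in NG2/A2B5. Adjusted over all genes, neither passed, with adjusted p-values of 0.546 and 0.862. Adjusted over the list alone, which has 4 measured members, Rflna passed in both, with adjusted p-values of 0.0126 and 0.00169. The first was 0.0503 without array I of O4, and with the mean of its 2 probes, of which the second was near background, the values were 0.624 and 0.308. Whether these arrays led the study to this gene is not given in the sources used here, so that count is not independent evidence. Between O4 and NG2/A2B5 the Rflna difference was -0.76 (interval -1.84 to 0.31).

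The genes Rflnb, Flna and Flnc had similar means in the 3 populations and passed in no contrast. Rflnb, the gene of refilin B, measured 2.66 ± 0.59 in O4 (SD, n = 3), 2.62 ± 0.52 in NG2/A2B5 (n = 2) and 2.66 ± 0.34 in NG2 (n = 3). Flna, the gene of the widely expressed filamin A, measured 6.07 ± 0.23 in O4, 5.80 ± 0.38 in NG2/A2B5 and 5.88 ± 0.44 in NG2. Flnc, the gene of the muscle filamin, measured -0.07, 0.03 and -0.15. As a set, the refilin and filamin genes had a camera p of 0.0434 in O4 against NG2 and 0.00874 in NG2/A2B5 against NG2, both with an adjusted p of 0.426. With an estimated correlation the p-values were 0.0875 and 0.0381, both with an adjusted p of 0.979. By fry, which asks whether members move one way on balance, the adjusted p-values were 0.00744 and 0.00338. These set tests used 3 of the genes, as Rflnb lacked a value on 1 array. In a fry test chosen after this was seen, Flna and Flnc without Rflna had p-values of 0.313 and 0.409.

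**Figure D2:**
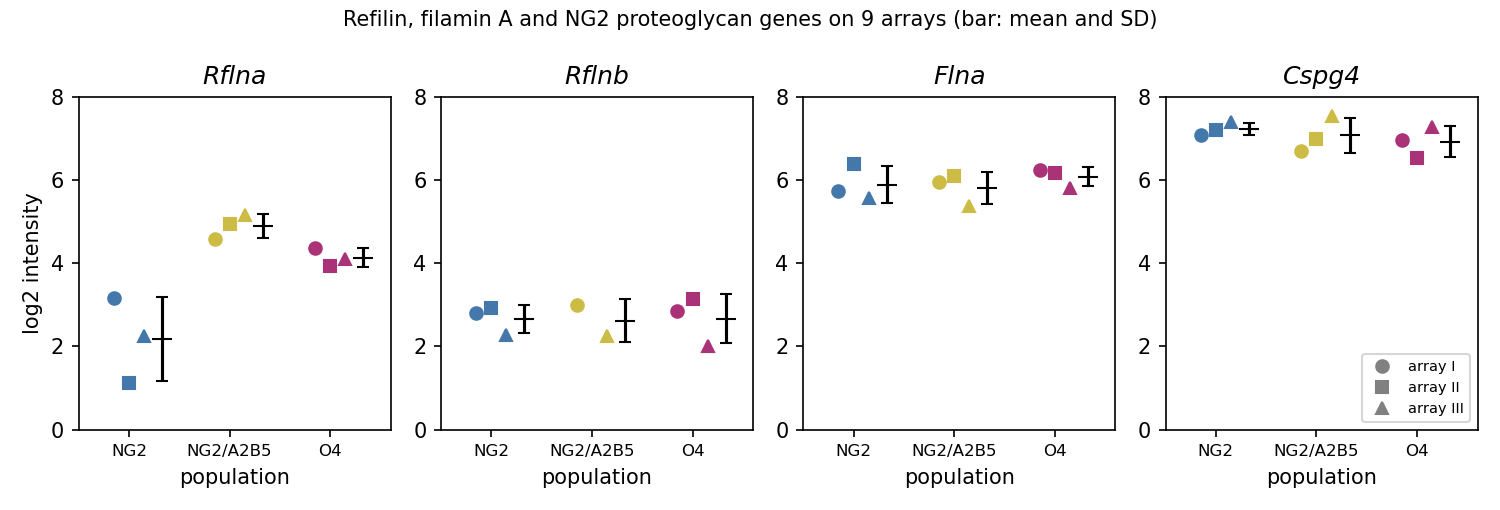
Log2 intensity of Rflna, Rflnb, Flna and Cspg4 on each array, by population, with the mean and SD beside the points. Rflna averaged 2.18 in NG2, 4.89 in NG2/A2B5 and 4.13 in O4, while the means of Flna lay between 5.80 and 6.07.

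The genes behind the sort antigens passed in no contrast. Cspg4, which encodes NG2, measured 6.92 ± 0.37 in O4, 7.07 ± 0.42 in NG2/A2B5 and 7.22 ± 0.15 in NG2, so that the cells sorted as NG2-negative had RNA for it at a difference of -0.30 from NG2 (interval -0.92 to 0.32). Ugt8, the enzyme that makes the galactolipid precursor of the O4 antigen, measured 1.63, 2.14 and 2.04 in O4, NG2/A2B5 and NG2. St8sia1, an enzyme of ganglioside synthesis, measured 0.96, 1.40 and 0.98. Gal3st1, which adds the sulfate, was not measured. For these genes 0 contrasts passed over all genes or adjusted over the list alone.

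In O4 against NG2, the comparison of the later marker with the earlier, Igkv28 was lower in O4 and no gene was higher. Igkv28 is an immunoglobulin kappa variable segment, a gene of B cells, and its readings in O4 were -0.112, -0.0432 and -0.0066 intensity units, all under 0, against 0.0511 to 0.181 in NG2. The size of its log2 difference, -8.05 (adjusted p 0.00458), was set by the small positive value put in place of those readings. With a floor at the 25th percentile it was 0.13. Every reading of the gene lay under that floor, so 0.13 is a difference between the floors alone. Limma on all 9 arrays called 0 genes higher and 1 lower of 12165, with 973 at an unadjusted p under 0.05. On only the 6 arrays compared, plain pooled-variance statistics called 0, with 922, and limma called 0, with 810. Among genes that did not pass, those with the smallest p and higher values in O4 were Igfbpl1, a relative of insulin-like growth factor binding proteins, at 1.50 (SE 0.21), Tmf1, a Golgi protein, at 1.40, and Rasgef1c, a Ras exchange factor, at 2.15. Mturn, which encodes maturin, differed by 1.55, near background (0.24 with that floor), and Ankrd35 by 1.61. Rasgef1c and Ankrd35 read under the 25th percentile on each NG2 array, and with the floor they differed by 1.46 and 1.31. The lower values included Myef2, a repressor of myelin basic protein transcription, at -1.01 (SE 0.14), Ripk1, a kinase of cell death signalling, at -0.81, Cop1, a ubiquitin ligase, at -1.07, and Clec2d, a lectin, at -1.56. Another probe, also above the 25th percentile, gave -0.15 for Myef2, -0.018 for Ripk1 and -1.06 for Rasgef1c. Each of these 9 had an adjusted p of 0.546.

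Of the lists in O4 against NG2, myelin genes split 18 higher and 14 lower (median 0.04), progenitor genes 15 and 9 (0.09) and lineage transcription factors 9 and 5 (0.08). Premyelinating genes split 8 and 9, galactolipid genes 3 and 5, ganglioside synthesis genes 4 and 9, and cholesterol synthesis genes 6 and 14. Filopodia and actin regulators split 22 and 17 (median 0.04), and actin cross-linking and adhesion genes 20 and 13. Cell cycle genes split 15 and 23, and matrix proteoglycans 11 and 11. Microglia markers had 12 of 18 positive values, with a median of 0.39 and a camera p of 0.0284 (adjusted 0.426). Many of them, among them Cx3cr1, C1qa, C1qc, Ptprc and Trem2, read near background, so the count and median rest partly on such readings. The microglia markers with the smallest p were Cd53 at 1.37 and C1qb at 1.31, both near background, and Laptm5 at 0.76. Laptm5 was -0.74 with the mean of its probes, the other of which was near background. Adjusted over the list alone, Cfap126 of the ependymal list was higher in O4 by 2.01 (adjusted p 0.0126, and 0.0520 without array II of NG2), as was Cnn1 of the pericyte list by 1.38 (0.0431, and 0.162 without array I of O4). Cnn1 had a mean of -2.87, near background, and was over 0.05 in 6 of the 9 fits that left out an array, all but those without I or III of NG2/A2B5 or I of NG2. It passed under 3 of 10 other settings, with 0.882 for the mean of its probes, of which the second differed by -0.95, 0.128 after quantile normalization and 0.351 with trend and robust estimates. Over all genes, 0 members of any list were called.

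O4 against NG2/A2B5 sets the later marker against cells with both early antigens. Igkv28 was again the gene that passed, at -7.64 (adjusted p 0.00681), a size set in the same way. With a floor at the 25th percentile it was 0.14, again a difference between the floors alone. Limma called 0 genes higher and 1 lower of 12165, with 399 at an unadjusted p under 0.05, and plain pooled-variance statistics called 0, with 464. Without array I of NG2/A2B5 the call was lost, and without array III of NG2/A2B5 there were 3 genes called higher. Among genes that did not pass, the smallest p-values in the higher direction belonged to Ereg, a ligand of the epidermal growth factor receptor, at 2.27 (SE 0.30, adjusted p 0.452), Fam236d at 1.32, Tmem104 at 1.45, Igfbpl1 at 1.18 and Sash3, an adaptor of lymphocytes, at 0.98. In the lower direction they were Sun1, a nuclear envelope protein, at -1.22 (SE 0.18, adjusted p 0.677), the kinase gene Map3k1 at -0.89, Mpc1l at -1.86 and Zfp455l1 at -0.73. Ereg, Map3k1 and Mpc1l were near background, and with that floor their differences were 0.40, 0.14 and 0.061. For Map3k1 every reading lay under the floor, so 0.14 is a difference between floors. Fam236d and Tmem104 read under the 25th percentile in NG2/A2B5, and Sun1 in O4, and with the floor they differed by 0.51, 0.76 and -0.68.

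Adjusted over the list alone, 3 members passed in O4 against NG2/A2B5, all higher in O4, while 0 passed over all genes. As that adjustment does not reach across lists and contrasts, some such passes are expected without any change. Pmp2 of the Schwann cell list, a myelin lipid-binding protein, was higher by 0.99 (0.0203, and 0.0788 without array I of O4, 0.0822 without III of O4, 0.0621 without II and 0.0898 without III of NG2/A2B5). Its log2 values were 0.47 to 0.72 in O4, -0.54 to -0.22 in NG2/A2B5 and -0.014 to 0.78 in NG2, so that O4 and NG2 overlapped. Cfap126, a gene of motile cilia, was higher by 1.64 (0.0385), with values over 0.05 without I (0.106) or II (0.0967) of O4, II (0.148) or III (0.0847) of NG2/A2B5, or I of NG2 (0.0638), and in 2 of 16 other settings (0.0502 after quantile normalization, 0.0652 with only the 6 arrays compared). Cd53, a leukocyte surface protein, was higher by 1.49 (0.0435), near background, with values over 0.05 in 7 of the 9 fits that left out an array (all but those without I of O4 or I of NG2), up to 0.190 without II of NG2/A2B5. It passed under 3 of 10 other settings, with 0.0845 after quantile normalization, 0.159 with the fixed block and 0.367 with trend and robust estimates. Other microglia markers were Itgam at 0.55 and C1qb at 1.34, the latter near background, and 10 of 18 were positive (median 0.24, camera adjusted p 0.426, estimated-correlation p 0.0766). Many of the 18 read near background. Of the myelin genes 14 were higher and 18 lower, with Lpar1, a lysophosphatidic acid receptor, at 0.82 (0.14 and 0.16 with its other probes) and Evi2a at 0.53. Nkx6-2, a transcription factor of maturing oligodendrocytes, differed by 1.22, and the split of its list was 8 and 6. Progenitor genes split 11 and 13, premyelinating genes 7 and 10, galactolipid genes 4 and 4, and cholesterol synthesis genes 9 and 11. Ganglioside synthesis genes split 4 and 9 (median -0.14, adjusted p 0.426), and filopodia and actin regulators 20 and 19.

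In NG2/A2B5 against NG2, the comparison of cells with and without A2B5, no gene passed in the model without the numeral, nor with the fixed block (lowest adjusted p 0.154). Limma called 0 genes in either direction of 12166, with 545 at an unadjusted p under 0.05 and a lowest adjusted p of 0.742, and plain pooled-variance statistics called 0, with 584. Without array III of NG2 there was 1 gene called higher, and without array III of NG2/A2B5 there were 3 called lower. Besides Rflna, the smallest p-values in the higher direction belonged to Abhd1, a hydrolase, at 2.12 (SE 0.36), Plcd3, a phospholipase C, at 2.07, Ifi30, a lysosomal thiol reductase, at 1.35, and Mdp1 at 0.85, with an adjusted p of 0.862. In the lower direction they were Cbln1, a secreted synapse organiser, at -1.45 (SE 0.18, adjusted p 0.742), Cd302, a lectin receptor, at -1.79, Plod1, a collagen lysyl hydroxylase, at -2.06 (both 0.846), Myef2 at -0.77 and Taar7a at -3.39, the last near background (-0.41 with a floor at the 25th percentile). Another probe, also above that percentile, gave 0.56 for Plcd3, 0.17 for Mdp1 and -0.14 for Myef2.

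Cell cycle genes leaned lower in NG2/A2B5 than in NG2, with 29 of 38 members negative and a median of -0.14, among them Kif20a at -0.32 and Top2a at -0.25. The camera p was 0.0294, its adjusted value 0.426, and with an estimated correlation the p was 0.537. Cell cycle exit genes had 7 of 8 negative values (median -0.27, adjusted p 0.426, estimated-correlation p 0.118), with Rbl2 at -0.93 (-0.67 with a floor at the 25th percentile) and Cdkn2c at -0.28 (0.16 and 0.0020 with its other probes). Of the myelin genes 18 were higher and 14 lower, of the progenitor genes 10 and 14, and of the lineage transcription factors 9 and 5. Filopodia and actin regulators split 19 and 20 and actin cross-linking and adhesion genes 17 and 16, with Itgb1, an integrin, at 0.50 (-0.20 with its other probe). In this contrast Rflna was the only list member that passed adjusted over the list alone, and 0 passed over all genes. With the fixed block, Hes5, Emid1, Abcc9, Cnn1 and Bst2 also passed over their lists, all higher in NG2/A2B5, but with trend and robust estimates added only Emid1 and Bst2 of these did. Another probe gave 0.065 for Abcc9 and, near background, -1.05 for Cnn1, -3.31 for Emid1 and 1.27 for Hes5.

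The remaining lists are given for O4 against NG2. Neural stem genes split 8 higher and 5 lower, notch, wnt and bmp targets 10 and 9, channels and receptors 23 and 20, and cell cycle exit genes 4 and 4. Astrocyte markers split 6 and 9, neuron markers 12 and 7, endothelial markers 8 and 4, pericyte markers 9 and 4, fibroblast markers 9 and 6, Schwann cell markers 4 and 4, and ependymal markers 5 and 0. Of the ependymal markers, Foxj1, Tmem212 and Drc12 read near background. Immediate early and heat shock genes split 8 and 13, and interferon response genes 12 and 7. Across all lists and contrasts, camera called 0 of 81 after adjustment, with 9 at an unadjusted p under 0.05. With an estimated correlation it called 0, with 1 at an unadjusted p under 0.05, and fry called 2 by direction and 0 in its mixed form.

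Over the 3 populations together, the F test called 1 gene, with 653 at an unadjusted p under 0.05. Igkv28 was called lower in O4 than in both other populations, with readings under 0 in O4. That call was lost with the numeral as a fixed block, with trend and robust estimates (0 genes each) and with a floor at the 25th percentile. As that floor lay over every reading of the gene, the last loss was fixed in advance. Without a block 0 genes were higher or lower in NG2/A2B5 or in NG2 than in both others.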

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

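All alternatives that leave out an array, and 11 other settings, were planned. Another 9 settings were chosen after seeing the data, as were the values adjusted over a list under each setting. The counts are given as higher and lower in O4 than NG2, O4 than NG2/A2B5 and NG2/A2B5 than NG2. As reported they were 0 and 1, 0 and 1, and 0 and 0, with 1 gene by the F test and 1 against both others. Quantile normalization and the fold limit gave the same counts, as did centred medians and a random block, for which genes against both others were not counted. Without dim genes, all counts were 0, as Igkv28 was not tested there. With the mean of a gene's probes, and also with all probes, 1 gene was higher in O4 than NG2, 1 was higher in NG2/A2B5 than NG2 and the F test called 2. With a fixed block all counts were 0, with 1597, 738 and 1057 genes at an unadjusted p under 0.05 and lowest adjusted p-values of 0.0878, 0.117 and 0.154. With only the 6 arrays compared, 0 were lower in O4 than NG2. With trend and robust estimates, the pairwise and F test counts were 0, and with plain statistics on the 6 arrays compared the pairwise counts were 0. By fry, 2 list tests passed by direction. Of the added settings, the fixed block with trend and robust estimates gave 75 and 49, 1 and 0, and 67 and 28, with 101 by the F test, 36 against both others and 1 for the refilin and filamin genes. The same without dim genes gave 175 and 126, 3 and 0, and 90 and 46, with 193 by the F test and 66 against both others. The fixed block with genes over a mean intensity of 0.5 gave 15 and 3, 0 and 0, and 54 and 20, with 43 by the F test, 10 against both others and 1 refilin gene. That intensity limit without a block gave 0 throughout, as did a floor at the 25th percentile. The fixed block with that floor gave 0 and 0, 0 and 0, and 1 and 0, with 1 by the F test and 0 against both others. The fixed block without dim genes gave 1 and 0, 0 and 0, and 1 and 0, with 0 by the F test and 0 against both others, and 0 throughout with quantile normalization or with all probes. The cause was not tested, apart from fewer genes or arrays where the setting says so. With 1 array left out, genes higher in O4 than NG2 ranged from 0 to 1 (1 without NG2 III) and lower from 1 to 2 (2 without each O4 array). Genes higher in O4 than NG2/A2B5 ranged from 0 to 3 (3 without NG2/A2B5 III) and lower from 0 to 2 (0 without NG2/A2B5 I, 2 without each O4 array). Genes higher in NG2/A2B5 than NG2 ranged from 0 to 1 (1 without NG2 III) and lower from 0 to 3 (3 without NG2/A2B5 III). The F test ranged from 1 to 4 and genes against both others from 0 to 4, highest without NG2/A2B5 III, list tests from 0 to 1 (1 without NG2/A2B5 II), and refilin and filamin calls were 0. Of 3246 values of 124 named gene and contrast pairs, 3194 kept their direction. The mean of a gene's probes reversed Laptm5 (-0.74) and Baiap2 (-0.013) in O4 against NG2 and Emid1 (-0.44) in NG2/A2B5 against NG2. With the floor, with and without the block, the sign changed for Igkv28 (0.13 against NG2 and 0.14 against NG2/A2B5), Map3k1 (0.14) and Mpc1l (0.061). For Igkv28 and Map3k1 the floor lay over every reading, so these signs are those of the floors and not of the genes. Rflna stayed higher than in NG2 under all 27 alternatives, from 1.42 to 2.44 in O4 (adjusted p 0.0561 to 0.813) and from 2.19 to 3.20 in NG2/A2B5 (adjusted p 0.0131 to 0.9999, called under 2). Adjusted over its list alone, it passed in both contrasts under 15 of 16 settings, all but the mean of probes, and without 8 and 9 of the 9 arrays. The numerals were checked as pairs: deviations from population means correlated over 0.1 for 4 of 9 pairs over all genes (0.0375 to 0.144), short of the rule that each pair pass. Over genes above the dim limit they did for 9 of 9 (0.194 to 0.424), and the most similar array of another population had the same numeral for 9 of 9 arrays. Signal over background limits the dim genes: between 291 and 352 probes per array read at or below 0.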

Other observations

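Chosen only after results were seen were the model with a block and trend, its splits, and the tests of gene families, Igkv28, the numerals and the most alike arrays. With the numeral as a fixed block and variance estimates that follow the intensity, 30 genes were lower in NG2 than in both other populations. Capg, which caps actin filaments, was higher than in NG2 by 1.26 in O4 (adjusted p 0.00639) and by 1.80 in NG2/A2B5 (1.47e-04). Mical1, which oxidises actin and takes filaments apart, was higher by 1.54 (0.0478) and 1.93 (0.0150), and Tppp3, a tubulin polymerization protein, by 1.05 (0.0130) and 1.10 (0.00431). Fxyd1, a regulator of the sodium pump, was higher by 1.33 (0.00148) and 1.54 (1.47e-04), Plcd3 by 1.66 (0.0147) and 2.07 (0.00172), and the glycolytic gene Aldoc by 0.68 (0.0381) and 0.78 (0.0196). Capg, Tppp3 and Fxyd1 were picked after their values were seen, and the fixed lists of filopodia and actin regulators and of actin cross-linking genes did not pass in this model (camera adjusted p 0.952 and 0.952 in O4 against NG2, 0.924 and 0.942 in NG2/A2B5 against NG2). Another 5 genes were higher in NG2 than in both others: Myef2, the repressor of myelin basic protein, Eif4e3, Nfatc2, RT1-S3 and Zmym6. Other probes above the 25th percentile showed less change, with 0.51 and 0.56 for Plcd3, -0.15 and -0.14 for Myef2, and -0.048 and -0.44 for Nfatc2. Plod1 alone was lower in NG2/A2B5 than in both others, and none passed for O4.

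In the same model Rflna was higher in NG2/A2B5 than in NG2 by 2.71 (adjusted p 0.0490) and in O4 by 1.95 (0.0805). The first ranged from 1.00e-05 without array I of NG2 to 0.283 without array III of NG2/A2B5 when 1 array was left out. It was also over 0.05 without array I of O4 (0.196), III of O4 (0.157), II of NG2/A2B5 (0.114) and III of NG2 (0.260). The second ranged from 5.96e-04 without I of NG2 to 0.254 without III of O4, and passed also without I of NG2/A2B5 (0.0103) and II of NG2 (0.0387). Without all arrays of I, II or III, the adjusted p was 9.00e-11, 0.0211 and 0.645 for the first, and 3.31e-07, 0.0823 and 0.467 for the second. Higher in O4 than in NG2 were Fabp12 by 2.52 (0.0147, or 2.09 with a floor at the 25th percentile), Cfap126 by 2.01 (0.0356), Emid1 by 1.91 (0.0289), Nnmt by 1.81 (0.0343), Wdr54 by 1.77 (0.0307, or 1.43 with the floor), Mob1b by 1.52 (0.00417, with another probe at 0.62) and Igfbpl1 by 1.50 (0.00666). Lower in O4 were Clec2d at -1.56 (0.0327), Nln at -1.12 (0.0241), the histone-reader gene Kmt2e at -0.96 (0.0147, with its other probes at -0.26 and -0.23), the autophagy gene Atg7 at -0.91 (0.0294) and the splicing gene Rbm25 at -0.89 (0.0307). Of the fixed lists, the tetraspanin gene Cd9 (-0.74, 0.0307), the brain proteoglycan gene Cspg5 (-0.63, 0.0406) and the collagen gene Col1a1 (-0.78, 0.0440) were lower in O4, and Gap43, a gene of growing processes, was higher (0.68, 0.0344, with another probe at 0.29). In NG2/A2B5 against NG2, Lox, which cross-links collagen, was lower at -2.67 (0.00431, or -2.09 with the floor), Plod1 at -2.06 (1.47e-04), Cbln1 at -1.45 (7.34e-04), Cd302 at -1.79 (5.16e-04), the transcription factor gene Ebf3 at -1.33 (8.49e-04) and Lpar1 at -0.94 (0.0164). Higher were Abhd1 by 2.12 (0.00405), Tmem69 by 2.41 (0.0256), Cisd3 by 1.71 (3.74e-04) and Bst2, an interferon response gene, by 1.99 (0.0278, or 1.32 with the floor). Other probes gave 0.49 for Ebf3, -0.63 and -0.16 for Lpar1 and 0.37 for Tmem69.

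That model is exploratory. It is 1 of 20 settings compared apart from left-out arrays, 11 planned and 9 added, and among those with the most calls, while planned settings called between 0 and 2 genes per contrast. Pairing by numeral was not settled before its calls were seen. It called 75 genes higher and 49 lower in O4 than in NG2, 1 and 0 against NG2/A2B5, and 67 and 28 in NG2/A2B5 than in NG2. Without array II of O4 the first pair was 4 and 1, without III of NG2 6 and 2, without III of O4 10 and 3, without I of O4 21 and 20, without I of NG2 30 and 4, without II of NG2 48 and 13, without II of NG2/A2B5 62 and 44, without III of NG2/A2B5 62 and 34, and without I of NG2/A2B5 199 and 143. For O4 against NG2/A2B5 the pair was 31 and 17 without I of NG2/A2B5, 3 and 1 without I of O4, 0 and 1 without II or III of O4, and 0 and 0 without any other array. For NG2/A2B5 against NG2 it was 10 and 9 without II of NG2/A2B5, 20 and 11 without III of NG2/A2B5, 22 and 8 without II of NG2, 22 and 16 without III of NG2, 57 and 16 without I of NG2, 61 and 26, 65 and 32, and 77 and 33 without II, III and I of O4, and 98 and 48 without I of NG2/A2B5. Without all arrays of numeral I the pairs for O4 against NG2, O4 against NG2/A2B5 and NG2/A2B5 against NG2 were 53 and 36, 35 and 21, and 105 and 46. Without II they were 1 and 1, 0 and 1, and 11 and 6, and without III 11 and 3, 0 and 1, and 21 and 16. On simulated data the model recovered 51% of genes changed 2-fold, with 6 false calls among 11825. The contrasts with NG2 share its arrays. Of 12025 genes with a value on every array, 33 were called the same way in both. Simulations without change call too few genes to give an overlap for comparison. Independent lists of these sizes would share 0.390 genes lower in NG2 and 0.0876 higher. The correlation of the fold changes was 0.543 against 0.497 in simulations (highest 0.552), and their covariance 0.267 against 0.216 (highest 0.260). Errors in the simulations were independent between genes, so their highest values may understate what variation shared within an array would give. As the NG2 arrays could not be divided between the contrasts, part of the overlap may come from the shared arrays.

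Other splits of the arrays gave the following. Without a block, O4 against NG2 called 1 gene and the highest other split 0, with 1 of 10 splits as large. O4 against NG2/A2B5 called 1 and the highest other 2 (3 of 10), and NG2/A2B5 against NG2 called 0 and the highest other 0 (10 of 10). With the block and trend the real values were 124, 1 and 95, the highest others 1, 0 and 0, and 1 of 10 splits was as large in each. Only 4 of the 10, the real one included, part the arrays of every numeral as the block needs. The highest other of these called 0 in each contrast. With 10 splits, or with 4, no share can be under 0.05. Over the 3 populations without a block, 24 of 100 splits drawn from 280 called at least the 1 gene of the real grouping, so chance is not excluded. The highest called 19, and the grouping by numeral, fitted separately, called 242, which points to a structure by numeral. Rearranging the populations within each numeral, 1 of 36 arrangements, the real one, called 101 genes with the block and trend. The highest other called 62 and the median of the others was 0. The arrangement with 62, and the next with 12 and 11, only exchanged O4 and NG2/A2B5 arrays and kept the NG2 arrays together. They are thus no reference for a difference of NG2 from the rest. Of the arrangements that moved NG2 arrays, the highest called 1.

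Arrays I of O4 and NG2/A2B5 were the most alike of the 27 pairs from different populations, with an SD of log2 differences of 0.462 (next 0.499). The pair ranked 1 of 27 after quantile normalization too (0.463). A scale factor on an array does not change this SD, so the rank is no test of scaling. For 56 genes called between these populations from II and III alone, the difference in I was 0.200 of that in II and III. Its bootstrap interval, 0.0505 to 0.259, resamples these genes and does not measure the spread between arrays. The ratios were 0.619 for O4 against NG2 and 0.450 for NG2/A2B5 against NG2. A candidate explanation is that the O4 and NG2/A2B5 fractions of I held nearly the same cells, but genes picked from II and III shrink in any other array, so a sort with less separation and a culture with smaller differences cannot be told apart.

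Igkv28 read under 0 on the 3 O4 arrays and at most 0.181 elsewhere. Its log2 values in O4, -11.70, -10.97 and -10.97, were all the smallest positive value of the array put in place of the reading. The call thus rests on that replacement. With a floor at the 25th percentile the higher of its adjusted p-values was 0.941. That floor replaced every reading of the gene, so the check could not have kept the call and decides nothing. Over the alternatives its adjusted p-values ranged from 0.00149 to 0.748 against NG2 and from 0.00159 to 0.9996 against NG2/A2B5. No biological explanation was tested.

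RNA processing genes leaned lower in O4 than in NG2, with 43 of 63 negative (median -0.14) and 2 called lower. So did chromatin and related genes, with 67 of 104 negative (median -0.13), 3 called lower and 1 higher. Both families were taken by the start of the gene symbol. The second held Kmt, Kdm, Chd, Ankrd, Usp, Zmym and Setd genes, not all of which are chromatin genes. All family tests by camera kept the numeral as a fixed block. Mitochondrial ribosomal, oxidative phosphorylation and zinc finger genes, also tested, had camera p-values of 0.108, 0.262 and 0.743 in this contrast. Adjusted over all families and contrasts, both leaning families had a camera p of 0.0135. Their unadjusted p-values were 0.00155 and 0.00226, but 0.160 and 0.219 with an estimated correlation. With called genes left out they were 0.00533 and 0.00485. For both families merged the p was 2.65e-04 with all genes and 9.38e-04 without the called, or 0.175 and 0.206 with an estimated correlation. Since the families were chosen after the calls were seen, this leaves open whether only the called members moved. A shift common to the arrays of a numeral would cancel in the differences within it, whose median over the merged families was negative in 3 of 3 numerals (-0.055, -0.25 and -0.11). By family the medians in I, II and III were -0.039, -0.29 and -0.013 for RNA processing, mostly from II, and -0.097, -0.18 and -0.14 for chromatin and related genes. As the families were picked from calls in this contrast, that count decides nothing, and a difference between the populations stays open as untested.

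Ribosomal protein genes had 36 of 40 positive values in O4 against NG2/A2B5, with a median of 0.25 and a camera p of 2.84e-05, but 0.345 with an estimated correlation, and medians by numeral of -0.11, 0.47 and 0.35.

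The numerals gave more calls than the populations, in a model with trend and robust estimates that keeps population as a term. Between III and II, 786 genes were higher and 1097 lower, between II and I 481 and 355, and between III and I 162 and 155. With eBayes alone these were 193 and 231, 11 and 17, and 0 and 0. Picked after their values were seen, the stress response genes Nupr1 (-4.14), Chac1 (-3.07), Slc7a11 (-3.60) and Mthfd2 (-2.22) were lower in III than in II, as was the matrix gene Tnc (-3.14), while Tnr (2.08), Fa2h (2.32) and Txnip (2.24) were higher. Of 81 list tests between numerals, 17 passed after adjustment and 0 with an estimated correlation. What the numerals stand for is not given in the sources used here.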
